A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

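Transcripts of 14 libraries were analysed from the deposited gene tables, and raw reads were not used here. Per the labels, total RNA was prepared with a column kit, mRNA was reverse transcribed and libraries were made with a transposase-based kit. The submitters' processing notes name Subread 1.6.0, featureCounts and limma with the genome builds mm10 and hg38, and give no order, annotation or filters. The authors deposited a mouse and a human table of counts, whole numbers of reads per gene without normalisation, with 27179 and 28395 entries; entries without a symbol (958 and 450) held at most 0.306% of a library's counts. The authors also deposited a table per library in log2 FPKM, a log2 value of fragments scaled to gene length and library size, for 14704 mouse and 12731 human genes; no label describes its offset or any further normalisation. The log2 FPKM values served as an alternative only. The 2 Irf4 flox/+ columns of the mouse count table share a name, so the labels alone do not give their replicate numbers and they were called a and b. No human genome annotation was held, so positions are given for mouse genes only.

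Groups followed the labels, with 2 libraries in each of 6 groups and 1 library each of follicular B cells and bone marrow plasma cells. Each of the 3 comparisons was fitted on its own 4 libraries with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr with its minimum count of 10, a quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Log2 fold changes are targeted over control, and values are TMM-scaled CPM (counts scaled to library size) with the SD of 2 libraries, scaled within the comparison, or over all libraries of the species for marker sums and reference libraries; immunoglobulin shares are percent of all counts. For a gene without a count in one group, the fold is a lower bound from a floor of 3 counts over that group. Floors cover counting error only, and p-values of single genes measure only the spread between these samples. Exact intervals of a share of genes and Fisher's exact test treat genes as independent units. Chi-square per degree of freedom between replicates was 37.2 to 266, so libraries of one group differed by far more than counting error. In tests on simulated data, edgeR recovered 4.48%, 29.9% and 56.7% of genes changed 4-fold at the spread of splenic plasma cells, MPC-11 and MM.1S, and called 1, 6 and 5 unchanged genes. DESeq2 recovered 34.3%, 56.7% and 65.7% and called 81, 49 and 58. Beside these false calls it recovered 1, 23 and 46 genes changed 2-, 4- and 8-fold at the splenic spread. The numbers were 9, 38 and 55 for MPC-11 and 21, 44 and 56 for MM.1S. In this simulation its adjusted p under 0.05 therefore did not hold false calls to that share. Camera recovered a set of 30 genes shifted 1.5-fold in each of the 3. Genes were drawn independently of each other in that simulation, so it does not test camera on lists whose genes move together.

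A set of 18 gene lists and 8 marker lists of other cell types was written before the data were examined, as were the comparisons, tests and alternatives unless stated otherwise. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation. The lists cover plasma cell identity, B cell identity, MHC class II presentation, ER chaperones, ER translocation, the amino acid and integrated stress response, oxidative phosphorylation, mitochondrially encoded genes, mitochondrial dynamics, glycolysis, cholesterol synthesis, the BCL2 family, the cell cycle, MYC and ribosome biogenesis, p53 targets, the interferon response, the proteasome and ribosomal proteins. The difference of effect between splenic plasma cells and MPC-11 was an interaction contrast over 8 libraries. Shared calls were tested with Fisher's exact test over genes tested in both, matched between species by symbol ignoring case. Lists of 200 genes each, highest in bone marrow plasma cells or in follicular B cells at a CPM of at least 10 and without immunoglobulin genes, were tested in the 3 comparisons. Immunoglobulin shares were compared with an exact permutation test.

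Genes were named by a rule written before the data were examined: Irf4 or IRF4; the 10 largest changes per direction among genes past the threshold with a mean CPM of at least 5 and groups that did not overlap, without immunoglobulin, T cell receptor, unnamed and sex-linked marker genes; up to 4 passing members per list; genes called in all 3 comparisons; the top genes of the difference of effect; and list members in the reference libraries. As edgeR called 3 genes in all, the rule was also applied to DESeq2's calls, a choice made after the data were seen. Among DESeq2's calls the rule was applied a second time to genes with reads in every library. Named outside the rule, chosen after values were seen, were Cxcr5, Irf8, Pax5, Prdm1, Edem2, Dnajb9, Sdf2l1, P4hb, Edem1, Ssr4, Mcm5, Cdc20, Ern1, ATF4, XBP1, members of the plasma cell identity list that did not pass in MPC-11, a passing member of a list beyond its first 4, single immunoglobulin genes, Cd22, Hrc, Scn4a and other genes known from muscle, and the shared genes listed.

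Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, limma-voom, limma on the deposited log2 FPKM, removal of immunoglobulin genes, a replicate block, leaving out each library in turn, a fit of all 10 mouse libraries, other sizes and minimum values for the cell-type lists, and a narrower set of immunoglobulin genes. Chosen after seeing the data were a replicate block on the log2 FPKM of splenic cells, a replicate block on the splenic counts and in the difference of effect after columns a and b were matched to replicates 1 and 2 by their values, the test of the lists in the interaction, signatures of 100 genes per direction of one comparison tested in another, scaling to library size alone without TMM, 2 parts of the bone marrow list at 10 CPM or more, the follicular list without markers of other cells, the tests of scaling and the muscle RNA test. The follicular B cell share each B cell gene would need, in TMM-scaled values, was also chosen then. Groups of 2 libraries were too small for a search for outliers or for other splits of the samples.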

Results

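RNA sequencing was done on 14 libraries in 8 groups, 10 from mouse and 4 from human cells. IRF4 is a transcription factor needed for plasma cells to form, and the series asked what it does in plasma cells that already exist. In the mouse arm, bone marrow carrying Irf4 flox/+ or Irf4 flox/- was grafted into congenic hosts, tamoxifen was given on days 1, 2, 7 and 8, and donor plasma cells were sorted from spleen on day 14, with 2 libraries per genotype. In the cell line arm, the mouse plasmacytoma line MPC-11 and the human myeloma line MM.1S received Cas9 with either a guide RNA against IRF4 or an empty vector. The lines were sorted on day 3 after doxycycline, with 2 libraries per condition. A single library each of splenic follicular B cells and bone marrow plasma cells served as reference. Mouse libraries held 18.7e6 to 27.0e6 counts and human libraries 19.3e6 to 21.6e6. The 2 count columns of the Irf4 flox/+ group carry the same name and are called a and b here.

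The targeted transcript was lower with the guide RNA in both cell lines but not in the splenic libraries labelled Irf4 flox/-. In MM.1S, IRF4 stood at 142 and 191 CPM (counts scaled to library size) with the guide against 489 and 434 with the empty vector, a log2 fold change of -1.47 ± 0.22 (SE, n = 2 per group; edgeR adjusted p = 0.199, DESeq2 adjusted p = 2.17e-08). In MPC-11, Irf4 stood at 276 and 146 CPM against 467 and 496, a log2 fold change of -1.19 ± 0.37 (SE; edgeR adjusted p = 0.592, DESeq2 adjusted p = 0.0762). In splenic plasma cells Irf4 (Entrez 16364; mm10 chromosome 13, 30749233 to 30766981) stood at 82.6 and 99.8 CPM in the flox/- libraries against 114 and 53.8 in the flox/+ libraries, a log2 fold change of 0.12 ± 0.43 (SE; edgeR adjusted p = 0.967). That direction turned to -0.33 without flox/+ library b and to -0.03 without flox/- library 2. Counts per gene do not show whether floxed exons were lost, so the genotype of these libraries rests on their labels.

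**Figure D1:**
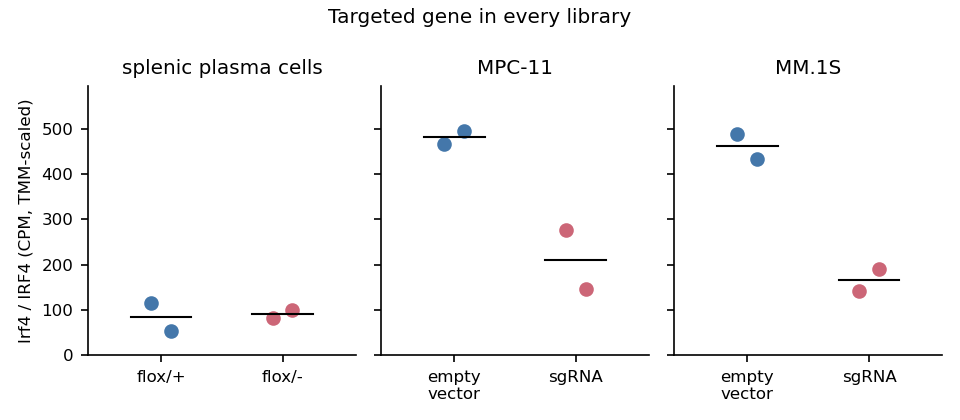
Irf4 or IRF4 in TMM-scaled CPM in each library, with points for libraries and lines for group means. Guide RNA libraries sit below both empty vector libraries in MPC-11 and MM.1S, while the flox/- libraries at 82.6 and 99.8 CPM lie between the flox/+ libraries at 53.8 and 114 CPM.

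The comparison of splenic plasma cells was set up to ask what the loss of IRF4 does to mature plasma cells in the animal. By their names, the flox/+ and flox/- genotypes differ in the other Irf4 allele before tamoxifen, and both received tamoxifen. Effects of that allele before treatment were therefore not separated from loss induced by tamoxifen. Genes of B cell identity were higher in the flox/- libraries, and genes of plasma cell identity and of protein folding and export in the endoplasmic reticulum (ER) were lower relative to the other genes. Of 30 measured B cell identity genes, 28 were higher, with a median log2 fold change of 1.73; of 28 ER chaperone and unfolded protein response genes, 28 were lower, with a median of -0.80. The immunoglobulin share of counts was 57.1% ± 2.40 (SD, n = 2) in the flox/- libraries and 76.4% ± 1.16 in the flox/+ libraries. Marker sums of macrophages, T cells, red cells and NK cells were also higher in both flox/- libraries. With immunoglobulin taking fewer counts, 90.5% of all genes were higher in the flox/- libraries when these were scaled to their size alone, a scaling chosen after the data were seen. The medians of ER chaperones, ER translocation, plasma cell identity and oxidative phosphorylation then turned to 0.09, 0.19, 0.06 and 0.43. For these medians, lower here means lower than the other genes. The ER chaperone list took 1.14% and 1.30% of counts with flox/- against 1.14% and 1.21% with flox/+. The plasma cell identity list did take a smaller share, 3.18% and 3.53% against 4.22% and 4.51%.

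B cell identity rose as a list (camera, adjusted p = 6.81e-12), with an adjusted p = 0.384 with an estimated correlation. Adjusted over the list alone, 15 members rose in edgeR, 0 fell and 15 did not pass. Ighd, the heavy chain of naive B cells, stood at 52.7 ± 18.9 CPM (SD) against 5.31 ± 0.845, and the chemokine receptor Cxcr5 had a log2 fold change of 3.90 ± 0.82 (SE). Cd83, an activation marker, had a log2 fold change of 2.36 ± 0.44 (SE). Irf8, a transcription factor of B cells and of myeloid cells, had one of 1.36 ± 0.29. Pax5 stayed near the floor, at 0.638 ± 0.104 CPM against 0.263 ± 0.372. MHC class II presentation rose as a list of 14 genes (median 0.70; camera, adjusted p = 2.25e-05, adjusted p = 0.313 with an estimated correlation), and 3 members rose when adjusted over the list alone. These were Ciita, the master regulator of the class II genes, at 53.5 ± 2.33 CPM against 0.556 ± 0.786, and the peptide loading genes H2-DMb2 (log2 fold change 2.92 ± 0.38, SE) and H2-Oa (3.71 ± 0.58). The median of B cell identity went to 1.13 without flox/- library 2, and that of MHC class II presentation to 1.10 without flox/+ library b.

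Plasma cell identity fell as a list of 24 genes, 20 of them lower (median -0.84; camera, adjusted p = 3.69e-08, adjusted p = 0.237 with an estimated correlation). Adjusted over the list alone, 5 members fell in edgeR and 0 rose. Xbp1, a driver of the secretory programme, stood at 1169 ± 90.2 CPM against 3211 ± 658, and Sdc1, the plasma cell surface marker CD138, at 270 ± 35.9 against 629 ± 3.78. Epcam (log2 fold change -1.55 ± 0.30, SE), Fkbp11 (-1.30 ± 0.32) and Ly6c1 (-1.94 ± 0.48) were the other members. Prdm1, which encodes the plasma cell regulator BLIMP-1, stood at 67.0 ± 23.7 CPM against 57.6 ± 1.53 and did not pass.

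ER chaperones and the unfolded protein response fell as a list (camera, adjusted p = 6.81e-12, adjusted p = 0.237 with an estimated correlation). No member passed in edgeR when adjusted over the list alone (0 of 28, with 11 lower at an unadjusted p under 0.05), while DESeq2 called 5, Edem2, Dnajb9, Sdf2l1, P4hb and Edem1. Edem2, which sends misfolded proteins to degradation, stood at 397 ± 17.5 CPM against 1005 ± 55.2. ER translocation and vesicle transport fell too, with 32 of 33 genes lower (median -0.70; camera, adjusted p = 3.11e-11, adjusted p = 0.237 with an estimated correlation). Ssr4, a part of the translocon complex, stood at 214 ± 34.2 CPM against 638 ± 32.7.

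Nuclear-encoded oxidative phosphorylation genes were lower in 69 of 75 cases and fell as a list (median -0.46; camera, adjusted p = 7.43e-08, adjusted p = 0.615 with an estimated correlation). Proteasome genes had a median of -0.23 (camera, adjusted p = 0.0146, adjusted p = 0.615 with an estimated correlation). Cell cycle and DNA replication rose, with 26 of 32 genes higher (median 0.88; camera, adjusted p = 6.57e-04, adjusted p = 0.237 with an estimated correlation); the replication helicase gene Mcm5 stood at 39.6 ± 2.85 CPM against 9.41 ± 2.98. Interferon response genes rose, 22 of 26 being higher (median 1.04; camera, adjusted p = 7.10e-04, adjusted p = 0.497 with an estimated correlation), and Oas2 alone passed when adjusted over the list alone. Scaled to library size alone, the proteasome turned to 0.67 and its call ended (camera, adjusted p = 0.984), as it did without flox/+ library b (median -0.13; adjusted p = 0.192), where oxidative phosphorylation went to -0.21. Without flox/- library 1 oxidative phosphorylation went to -0.71 and the interferon response to 0.53, while without flox/- library 2 the proteasome stood at -0.14 and oxidative phosphorylation at -0.29.

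The other 9 lists did not pass in camera. Their medians were -0.31 for the amino acid and integrated stress response, 0.71 for mitochondrially encoded genes, 0.40 for glycolysis, 0.17 for mitochondrial dynamics, 0.15 for cholesterol and fatty acid synthesis, 0.12 for the BCL2 family, 0.17 for MYC and ribosome biogenesis, 0.17 for p53 targets and 0.22 for ribosomal proteins. The mean of the amino acid list was 0.19, opposite in sign to its median, and camera placed mitochondrial dynamics and ribosomal proteins on the lower side although their medians were above 0. Mitochondrially encoded genes passed without flox/+ library a (median 2.04; camera, adjusted p = 5.19e-04), without flox/- library 2 (1.13; adjusted p = 0.0271) and with a replicate block chosen after the data were seen (0.93; adjusted p = 0.00619), but stood at 0.02 without flox/- library 1 and at 0.04 without flox/+ library b. The amino acid list passed without a filter on low counts (camera, adjusted p = 0.0225), without immunoglobulin genes (adjusted p = 0.0174) and without flox/+ library a (adjusted p = 0.0111) or flox/- library 2 (-0.51; adjusted p = 0.0463), and stood at -0.05 without flox/+ library b, where mitochondrial dynamics turned to -0.03, while ribosomal proteins turned to -0.24 and passed without flox/- library 1 (adjusted p = 0.0335).

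Markers of other cell types moved with the genotype labels; their sums are scaled over all 10 mouse libraries, as are the values of the reference libraries, and do not compare with values scaled within a comparison. Macrophage and monocyte markers summed to 7320 and 622 CPM in flox/- libraries 1 and 2 against 512 and 197 in the flox/+ libraries, T cell markers to 192 and 473 against 16.6 and 39.1, erythroid markers to 923 and 50.3 against 49.2 and 5.49, and NK cell markers to 22.9 and 50.4 against 1.75 and 0.600. The sum of plasmacytoid and dendritic cell markers, carried by Tcf4, was 170 and 183 CPM against 240 and 235, and its members did not all go the same way. Stromal markers (66.6 and 52.1 CPM against 54.5 and 36.5), platelet markers (2.13 and 0.300 against 2.12 and 1.54) and neutrophil markers (0 and 0.400 against 3.69 and 0) differed less. Ribosomal RNA transcripts differed in the opposite sense. Rn45s, scaled within the comparison, stood at 605 and 359 CPM in the flox/- libraries against 6774 and 1405 in the flox/+ libraries.

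**Figure D2:**
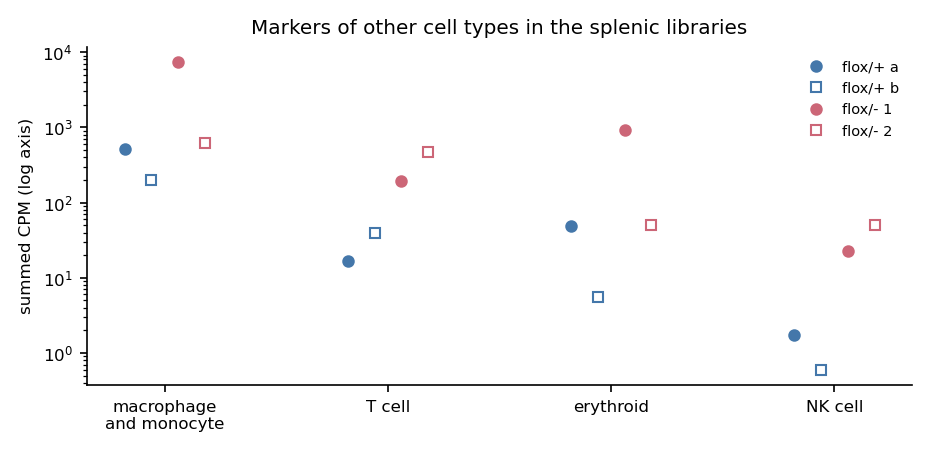
Summed CPM of marker genes of 4 other cell types in each splenic library, scaled over all 10 mouse libraries, on a log axis. Both flox/- libraries lie above both flox/+ libraries for each type, and library 1 reaches 7320 CPM for macrophage and monocyte markers.

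Of 11887 genes tested in splenic plasma cells, edgeR called 0 higher and 0 lower, the smallest adjusted p being 0.260. At an unadjusted p under 0.05, 1026 genes were higher and 458 lower (1484 in all, where 594 were expected by chance), and DESeq2 called 433 higher and 202 lower. Among DESeq2's calls, the genes with the largest higher values had no count in the flox/+ libraries and included markers of T and NK cells, the surface receptor Cd6 (at least 354-fold higher), the transcription factor Eomes (at least 218-fold) and the cytotoxic granule gene Nkg7 (at least 197-fold), beside the transporter Abcc3 (at least 585-fold). Among genes with counts in each of the 4 libraries, Znfx1, an interferon-induced helicase, stood at 33.2 and 33.9 CPM against 0.760 and 0.159. The 3 largest lower values outside ribosomal RNA were those of Oosp1 (log2 fold change -2.55 ± 0.35, SE; DESeq2 adjusted p = 1.95e-07), Spag6 (-2.35 ± 0.52) and the protease inhibitor Slpi (-2.26 ± 0.47). In 44.1% of genes the groups did not overlap, where chance gives 33.3%. With simulated changes, edgeR at this spread recovered 33.3% of genes changed 8-fold and 4.48% of those changed 4-fold; DESeq2 recovered 69.7% and 34.3% but called 81 unchanged genes.

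The comparison in MPC-11 asks what loss of IRF4 does in a mouse plasma cell tumour line. ER chaperone genes and cell cycle genes were lower with the guide RNA, and B cell identity genes were higher. In 25 of 28 ER chaperone genes the value was lower (median -0.62), as it was in 28 of 32 cell cycle genes (median -0.81). Single genes that passed in edgeR were Mybph and Neurl3, both higher. Mybph, a muscle myosin-binding protein gene (Entrez 53311; mm10 chromosome 1, 134193418 to 134201237), had 0 counts with the empty vector and stood at 87.8 and 173 CPM with the guide, at least 1714-fold higher (edgeR adjusted p = 0.0271). Neurl3, a ubiquitin ligase gene (Entrez 214854; mm10 chromosome 1, 36264602 to 36274674), stood at 77.0 and 93.0 CPM against 1.76 and 2.33 (log2 fold change 5.37 ± 0.44, SE; edgeR adjusted p = 0.0271). Both calls ended with libraries scaled to their size alone (edgeR adjusted p = 0.163), with Neurl3 at a log2 fold change of 5.18. With a replicate block both ended too (edgeR adjusted p = 0.222), with Neurl3 at 5.38 ± 0.51 and the residual degrees of freedom going from 2 to 1.

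ER chaperones and the unfolded protein response fell as a list in MPC-11 (camera, adjusted p = 5.49e-10, adjusted p = 0.360 with an estimated correlation). Adjusted over the list alone, 5 members fell in edgeR and 0 rose. Hspa5, the chaperone BiP, stood at 1237 ± 26.3 CPM (SD) against 2584 ± 537, and Hsp90b1, the chaperone GRP94, at 970 ± 36.6 against 2182 ± 388. Creld2 (log2 fold change -1.21 ± 0.33, SE), Dnajb11 (-1.04 ± 0.29) and Ern1, the stress sensor IRE1 (-1.03 ± 0.29), were the others. ER translocation and vesicle transport had 28 of 33 genes lower (median -0.50; camera, adjusted p = 1.83e-05, adjusted p = 0.360 with an estimated correlation). Oxidative phosphorylation had 68 of 75 lower (median -0.39; camera, adjusted p = 1.83e-05, adjusted p = 0.609 with an estimated correlation) and the proteasome 24 of 27 (median -0.25; camera, adjusted p = 0.0163, adjusted p = 0.634 with an estimated correlation). Without empty vector library 1 the calls of oxidative phosphorylation (median -0.02; camera, adjusted p = 0.650) and of the proteasome, which turned to 0.01 (camera, adjusted p = 0.992), ended, and ER translocation went to -0.32. Without guide library 1 both ended as well (medians -0.21 and -0.20; camera, adjusted p = 0.236 and 0.321).

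Cell cycle and DNA replication fell as a list in MPC-11 (camera, adjusted p = 5.49e-10, adjusted p = 0.518 with an estimated correlation), with 0 members passing in edgeR when adjusted over the list alone, 12 lower and 1 higher at an unadjusted p under 0.05, and 1 called lower by DESeq2. That gene, the mitotic activator Cdc20, stood at 165 ± 33.7 CPM against 365 ± 13.7. B cell identity rose, 10 of 11 measured genes being higher (median 0.93; camera, adjusted p = 7.34e-04, adjusted p = 0.360 with an estimated correlation). Its passing members, adjusted over the list alone, were Id3, an inhibitor of E proteins, at 12.2 ± 3.96 CPM against 1.31 ± 0.0816, and Cd79b, a B cell receptor subunit, at 920 ± 9.64 against 356 ± 116. Mitochondrially encoded genes rose, with 13 of 13 higher (median 0.69; camera, adjusted p = 0.00164, adjusted p = 0.608 with an estimated correlation), and so did MHC class II presentation (median 0.37; camera, adjusted p = 0.0196, adjusted p = 0.519 with an estimated correlation). Plasma cell identity did not pass, with 12 genes higher and 12 lower (median -0.12; camera, adjusted p = 0.125). Within it Tnfrsf17, the receptor BCMA, stood at 115 ± 7.50 CPM against 304 ± 56.9 and Sdc1 at 340 ± 61.1 against 682 ± 15.9, while Slamf7 stood at 236 ± 51.4 against 118 ± 15.6; none of the 3 passed in edgeR. The call of mitochondrially encoded genes ended without empty vector library 1 (median 0.23; camera, adjusted p = 0.650) or guide library 2 (0.07; adjusted p = 0.421), and that of MHC class II presentation without empty vector library 2 (0.21; adjusted p = 0.387) or guide library 1 (0.08; adjusted p = 0.188), the latter taking the cell cycle to -0.52.

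The medians of the other lists were 0.23 for p53 targets (camera, adjusted p = 0.0666), 0.45 for the interferon response (adjusted p = 0.0550), -0.03 for the amino acid and integrated stress response, -0.07 for mitochondrial dynamics, 0.20 for glycolysis, 0.05 for cholesterol and fatty acid synthesis, 0.21 for the BCL2 family, 0.17 for MYC and ribosome biogenesis and -0.16 for ribosomal proteins. The interferon list passed without a filter on low counts (camera, adjusted p = 0.00384), with a replicate block (adjusted p = 0.0369), without empty vector library 1 (median 0.66; adjusted p = 0.0401) or 2 (0.68; adjusted p = 0.00973) and without guide library 2 (0.34; adjusted p = 0.00814), while p53 targets passed without empty vector library 1 (0.65; adjusted p = 0.00733) and turned to -0.13 without library 2. Without empty vector library 2 plasma cell identity turned to 0.07 and cholesterol synthesis (0.20; camera, adjusted p = 0.0404), MYC and ribosome biogenesis (0.32; adjusted p = 0.0106) and ribosomal proteins (-0.34; adjusted p = 0.00355) passed, the last also without guide library 2 (-0.60; adjusted p = 4.19e-04).

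Of 10670 genes tested in MPC-11, edgeR called 2 higher and 0 lower. At an unadjusted p under 0.05, 372 were higher and 273 lower, and DESeq2 called 110 higher and 49 lower. The unadjusted count was 645 in all, where 533.5 were expected by chance. In 33.5% of genes the groups did not overlap, close to the 33.3% that chance gives. DESeq2's calls included 2 further genes known from muscle with no counts with the empty vector, the myogenic transcription factor Myog (at least 339-fold higher; DESeq2 adjusted p = 4.34e-09), which lies close to Mybph (chromosome 1, 134290004 to 134292548), and the muscle ubiquitin ligase Trim63 (at least 243-fold). Itih5 (at least 260-fold higher) and Rapgef3 (at least 131-fold higher) also had no counts with the empty vector. The glutamate transporter Slc1a1 had no counts with the guide and was at least 372-fold lower, Pxmp2 had a log2 fold change of -4.27 ± 0.67 (SE) and Tram2, which takes part in translocation into the ER, of -2.60 ± 0.37. Without empty vector library 2, edgeR called 21 genes higher and 3 lower; without guide library 1 it called 15 and 22, and without guide library 2 it called 16 and 9. Without empty vector library 1 the call of 2 genes went to 1. With limma-voom in place of edgeR, 0 genes were called higher and 0 lower. Marker sums of T cells stayed under 1 CPM in the 4 MPC-11 libraries; those of macrophages were 1308 and 933 CPM with the guide and 1137 and 1261 with the empty vector, from at most 2 genes.

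The comparison in MM.1S asks the same of a human myeloma line. With the guide RNA, genes of the cell cycle, of amino acid synthesis and transport and of plasma cell identity were lower, and p53 target genes were higher. In 30 of 32 cell cycle genes the value was lower (median -0.60), as it was in 25 of 27 amino acid and integrated stress response genes (median -0.72), while 19 of 20 p53 targets were higher (median 0.70). CYP26A1, which breaks down retinoic acid (Entrez 1592), fell from 338 and 316 CPM to 25.1 and 19.5 (log2 fold change -3.88 ± 0.24, SE; edgeR adjusted p = 0.0180), the only gene edgeR called over all genes tested.

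Cell cycle and DNA replication fell as a list in MM.1S (camera, adjusted p = 6.95e-14, adjusted p = 0.381 with an estimated correlation). Adjusted over the list alone, 14 members fell in edgeR and 0 rose. RRM2, the ribonucleotide reductase subunit, stood at 207 ± 40.7 CPM (SD) against 613 ± 230, the D-type cyclin CCND2 at 615 ± 62.5 against 1209 ± 149, and the helicase genes MCM6 (log2 fold change -1.11 ± 0.21, SE) and MCM7 (-0.98 ± 0.24) were lower as well. The amino acid and integrated stress response fell (camera, adjusted p = 2.21e-13, adjusted p = 0.381 with an estimated correlation), and 8 members fell when adjusted over the list alone. PHGDH and PSAT1, enzymes of serine synthesis, stood at 66.2 ± 2.58 against 218 ± 106 CPM and at 78.6 ± 12.2 against 237 ± 118. The cystine transporter SLC7A11 had a log2 fold change of -2.68 ± 0.65 (SE), and ATF4, the transcription factor of this response, of -1.03 ± 0.31. The median of the amino acid list went to -0.39 without empty vector library 1 and to -1.16 without library 2.

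The p53 targets rose (camera, adjusted p = 3.89e-10, adjusted p = 0.289 with an estimated correlation), and 5 members rose when adjusted over the list alone. ZMAT3 stood at 10.8 ± 1.39 CPM against 1.37 ± 0.246, the death receptor FAS at 20.5 ± 0.996 against 5.12 ± 0.279, PHLDA3 at 34.1 ± 3.54 against 7.95 ± 2.95 and PLK2 at 68.5 ± 25.1 against 16.2 ± 5.62. The empty vector carries no guide RNA, so effects of DNA cutting on these genes were not separated from loss of IRF4. Plasma cell identity fell, 13 of 21 genes being lower (median -0.32; camera, adjusted p = 1.61e-04, adjusted p = 0.289 with an estimated correlation). Its members that fell, adjusted over the list alone, were TNFRSF17 (154 ± 22.2 CPM against 540 ± 139), SLAMF7 (482 ± 77.6 against 849 ± 86.0) and IRF4, itself the target of the guide. XBP1 stood at 2230 ± 10.6 CPM against 2230 ± 26.9. B cell identity rose, 14 of 17 being higher (median 0.49; camera, adjusted p = 0.00103, adjusted p = 0.289 with an estimated correlation), with FCMR, the receptor for IgM, at 665 ± 17.6 CPM against 232 ± 10.4. Its median went to 0.76 without empty vector library 2.

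ER chaperones fell less far than in the mouse cells, 21 of 28 genes being lower (median -0.22; camera, adjusted p = 0.00103, adjusted p = 0.289 with an estimated correlation); whether the effects differ between species was not tested. SEL1L, a part of the ER degradation machinery, had a log2 fold change of -1.56 ± 0.24 (SE), and MANF stood at 31.4 ± 1.36 CPM against 71.3 ± 1.37, the 2 members that fell when adjusted over the list alone. Cholesterol and fatty acid synthesis fell (median -0.30; camera, adjusted p = 1.22e-05, adjusted p = 0.304 with an estimated correlation), with INSIG1 and HMGCS1 as members that fell when adjusted over the list alone. The proteasome had 27 of 27 genes lower (median -0.28; camera, adjusted p = 2.36e-04, adjusted p = 0.617 with an estimated correlation). ER translocation (median -0.13; camera, adjusted p = 0.00335, adjusted p = 0.607 with an estimated correlation) and MHC class II presentation (median -0.30; camera, adjusted p = 0.0113, adjusted p = 0.564 with an estimated correlation) also fell. Oxidative phosphorylation fell (median -0.16; camera, adjusted p = 0.00877, adjusted p = 0.812 with an estimated correlation). Interferon response genes rose, 20 of 25 being higher (median 0.48; camera, adjusted p = 2.36e-04, adjusted p = 0.381 with an estimated correlation). Without empty vector library 2 the calls of the proteasome (median -0.07; camera, adjusted p = 0.393), ER translocation (-0.13; adjusted p = 0.285) and oxidative phosphorylation, which turned to 0.03 (adjusted p = 0.475), ended. The call of MHC class II presentation ended without empty vector library 1 (-0.41; camera, adjusted p = 0.0725) or guide library 2 (-0.19; adjusted p = 0.132), the latter ending oxidative phosphorylation too (-0.13; adjusted p = 0.0747), while the interferon response went to 0.77 without empty vector library 1.

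Glycolysis (median -0.24), the BCL2 family (0.16), MYC and ribosome biogenesis (-0.11) and ribosomal proteins (0.09) did not pass, nor did mitochondrial dynamics (camera, adjusted p = 0.892). FAS, a member of the BCL2 family list too, was its only member to pass when adjusted over the list alone. Mitochondrially encoded genes were not measured in MM.1S. Glycolysis passed without a filter on low counts (camera, adjusted p = 0.0438), with a replicate block (-0.26; adjusted p = 0.00888) and without empty vector library 2 (-0.40; adjusted p = 9.57e-04) or guide library 1 (-0.63; adjusted p = 1.56e-07), and turned to 0.07 without guide library 2. MYC and ribosome biogenesis passed on the lower side without empty vector library 1 (-0.41; camera, adjusted p = 7.52e-04) or guide library 2 (-0.34; adjusted p = 0.00348) and on the higher side without empty vector library 2 (0.24; adjusted p = 0.00940), and ribosomal proteins passed without empty vector library 2 (0.23; adjusted p = 0.00262) or guide library 2 (0.21; adjusted p = 0.00696).

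Of 12696 genes tested in MM.1S, edgeR called 0 higher and 1 lower, with 688 higher and 582 lower at an unadjusted p under 0.05. The unadjusted count was 1270 in all, where 634.8 were expected by chance. In 41.3% of genes the groups did not overlap, where chance gives 33.3%. DESeq2 called 195 higher and 179 lower. Among DESeq2's calls, BRINP2 (at least 192-fold higher) and KRT15 (at least 151-fold higher) had no counts with the empty vector. The heparan sulphate proteoglycan SDC2 (log2 fold change 3.34 ± 0.46, SE; DESeq2 adjusted p = 2.91e-08) and the fractalkine receptor CX3CR1 (2.76 ± 0.41) were higher. The chemokine CCL3 stood at 439 and 262 CPM against 3865 and 2866 (-3.26 ± 0.30; DESeq2 adjusted p = 8.99e-28), and SMOC1 (-4.32 ± 0.68), CAV2 (-2.58 ± 0.29) and the mitochondrial folate enzyme ALDH1L2 (-2.54 ± 0.32) were lower. Without empty vector library 1, 677 genes were called higher and 289 lower in edgeR, and without library 2, 61 and 56. Without guide library 2, edgeR called 0 genes lower, and without guide library 1 it called 2. Marker sums in MM.1S were 84.1 and 75.9 CPM with the guide against 80.2 and 81.5 for T cells and 94.1 and 76.6 against 109 and 83.9 for macrophages, 27.8 and 26.3 against 76.3 and 60.6 for stromal cells, 44.3 and 45.9 against 71.1 and 76.2 for red cells, and 426 and 391 against 311 and 298 for plasmacytoid and dendritic cells.

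**Figure D3:**
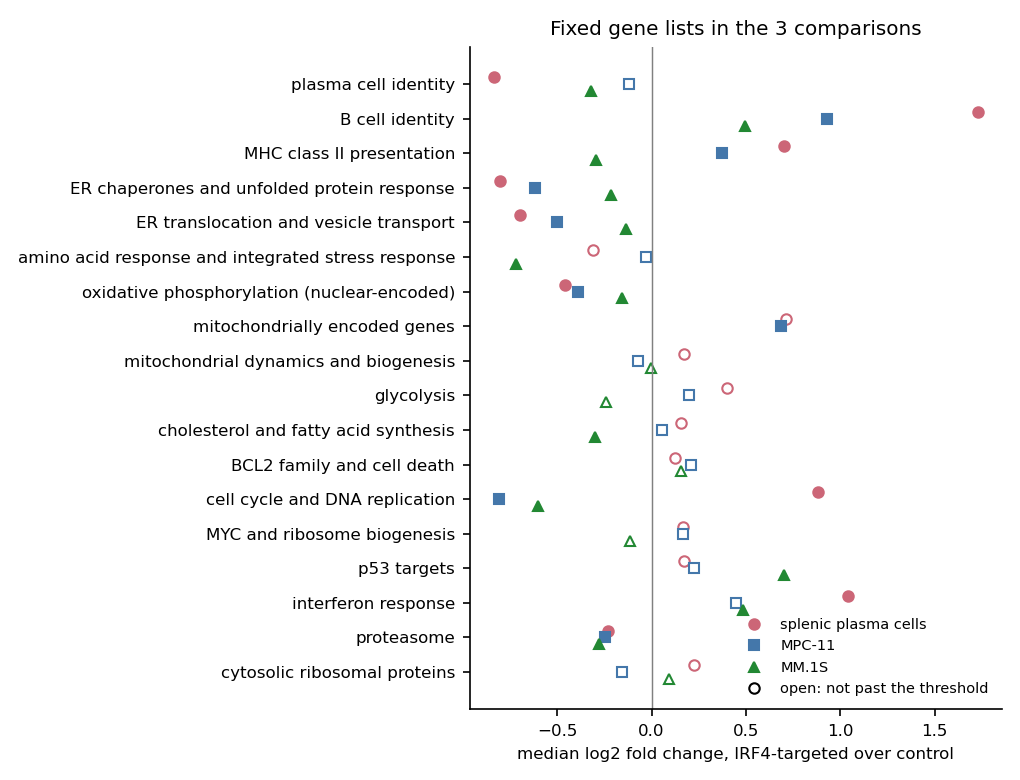
Median log2 fold change of each fixed gene list in the 3 comparisons, filled where camera with its preset correlation passed. With an estimated correlation 0 lists passed in any comparison.

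**Figure D4:**
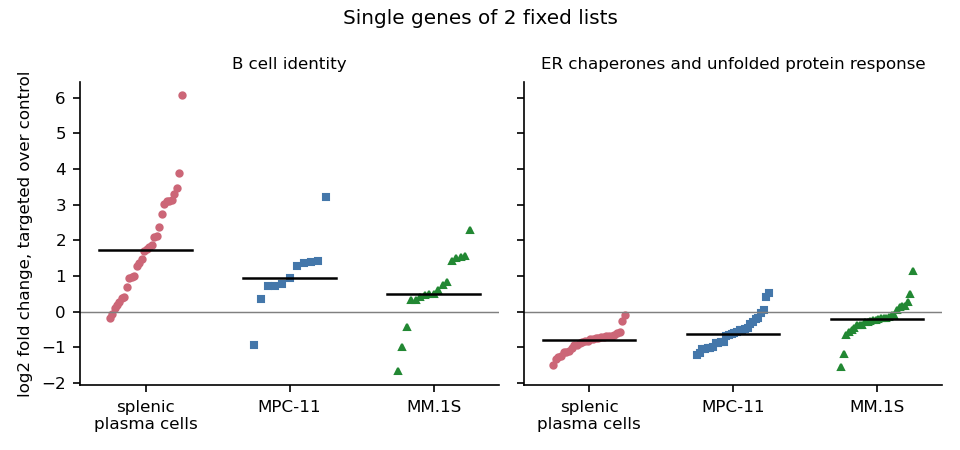
Log2 fold change of each member of 2 lists in the 3 comparisons, points being genes and lines medians. After TMM scaling all 28 ER chaperone genes lie below 0 in splenic plasma cells, 25 in MPC-11 and 21 in MM.1S.

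Calls shared between comparisons were counted next. With edgeR's calls, 0 genes were shared in any pair of comparisons. With DESeq2's calls, splenic plasma cells and MPC-11 shared 10 higher genes where 1.57 were expected (Fisher's exact test, adjusted p = 1.06e-05), among them Neurl3, Gsn, Id3 and Ltb, and 4 lower genes, Eaf2, Rcbtb2, Sdc1 and Txndc11 (adjusted p = 4.63e-04 in Fisher's exact test). Splenic plasma cells and MM.1S shared 17 higher genes where 3.63 were expected (Fisher's exact test, adjusted p = 6.52e-07), among them Plk2, Icam1 and Laptm5, and 1 lower gene, Kdelr1 (Fisher's exact test, adjusted p = 0.485). MPC-11 and MM.1S shared 4 higher and 3 lower genes, the lower ones being Cd44, Rfc2 and Tnfrsf17 (Fisher's exact test, adjusted p = 0.0137). In no case was a gene called in all 3 (0 higher and 0 lower of 8046 tested in all). Genes are not independent replicates in these tests, and DESeq2's calls held many unchanged genes in simulation. Markers of macrophages and T cells moved with the splenic groups, and the shared higher genes include the myeloid genes Itgam and Cx3cr1 (spleen and MM.1S) and Tyrobp (spleen and MPC-11), so the splenic side of an overlap was not separated from RNA of other cells.

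Between splenic plasma cells and MPC-11 the difference of effect was tested directly. Of 12993 genes, edgeR called 0, with 807 at an unadjusted p under 0.05, and DESeq2 called 181. In the same model the fixed lists were tested after the data were seen. Cell cycle and DNA replication was higher in spleen and lower in MPC-11, a median difference of 1.72 (camera, adjusted p = 2.43e-16, adjusted p = 0.0548 with an estimated correlation). Plasma cell identity was lower in spleen by a median of -0.55 relative to MPC-11 (camera, adjusted p = 1.61e-05, adjusted p = 0.0548 with an estimated correlation). In that test 4 of 18 lists passed, and 0 passed with an estimated correlation.

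Follicular B cells and bone marrow plasma cells, with 1 library each and no test, served to define genes of either type. Sex-linked transcripts differed between them, the Y-linked Ddx3y with 941 counts against 25 and Xist with 0 against 199. Sex was therefore not separated from cell type in these lists. Irf4 stood at 376 CPM in bone marrow plasma cells and 55.1 in follicular B cells, Prdm1 at 161 against 1.12 and Xbp1 at 5306 against 139. Of 24 plasma cell identity genes 23 were higher in bone marrow plasma cells, and Cd38, at 36.9 against 239 CPM, was the exception. All 30 B cell identity genes were lower, among them Fcer2a (0.454 against 812 CPM) and Cr2 (1.54 against 482). Of genes higher in follicular B cells, 180 of 191 measured were higher in the splenic flox/- libraries (94.2%, exact 95% interval 89.9 to 97.1; median log2 fold change 2.00; camera, adjusted p = 2.70e-32, adjusted p = 0.0486 with an estimated correlation); without 5 red cell markers among them it was 175 of 186 (94.1%). In MPC-11 the share was 72.9% (median 0.54; camera, adjusted p = 2.86e-06, adjusted p = 0.0679 with an estimated correlation) and in MM.1S 62.0% (camera, adjusted p = 0.121). Of genes higher in bone marrow plasma cells, 61 of 183 measured (33.3%) were higher in the splenic flox/- libraries (median -0.42; camera, adjusted p = 2.33e-06, adjusted p = 0.138 with an estimated correlation), and 66.1% with libraries scaled to their size alone (median 0.46). The share was 44.1% in MPC-11 (camera, adjusted p = 0.101) and 40.4% in MM.1S (camera, adjusted p = 0.00687, adjusted p = 0.327 with an estimated correlation). In MM.1S the bone marrow call ended with 100 genes per list (camera, adjusted p = 0.113), and the follicular list passed with 400 genes (adjusted p = 0.0197) or a CPM of at least 50 (adjusted p = 0.00318). In spleen the bone marrow median went to -0.69 at that CPM and to -0.63 with 100 genes, and the follicular median in MPC-11 to 0.92 with 100 genes and 0.28 with 400.

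Immunoglobulin transcripts were compared as a share of all counts. In splenic plasma cells the flox/- libraries stood at 57.1% ± 2.40 (SD) and the flox/+ libraries at 76.4% ± 1.16, without overlap (exact permutation test, two-sided p = 0.333, the smallest that 2 against 2 libraries allow). Ighm had 3352967 and 2405532 counts in the flox/- libraries against 1110286 and 1093948, and Ighg2c took 3.71% and 4.93% of counts against 12.3% and 9.56%. In MPC-11 the share was 31.5% ± 0.758 with the guide and 25.7% ± 11.4 with the empty vector (exact permutation test, p = 1), empty vector library 2 standing apart at 17.7%. In MM.1S it was 3.45% ± 0.273 against 4.56% ± 0.0567 (exact permutation test, p = 0.333), and the difference changed from -1.11 to 0.299 percentage points when constant regions and the joining chain alone were counted.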

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

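The tests of gene lists in the interaction were chosen only after the result was seen. Each list here was picked out because its effect differed between splenic plasma cells and MPC-11 in the interaction contrast with camera's preset correlation, and none of the 4 passed with an estimated correlation.

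Cell cycle and DNA replication genes were higher in the splenic flox/- libraries (median log2 fold change 0.88) and lower in MPC-11 with the guide RNA (-0.81), a median difference of 1.72 (camera, adjusted p = 2.43e-16, adjusted p = 0.0548 with an estimated correlation). Plasma cell identity genes were lower in spleen (-0.84) and near even in MPC-11 (-0.12), a median difference of -0.55 (camera, adjusted p = 1.61e-05, adjusted p = 0.0548 with an estimated correlation). ER translocation and vesicle transport genes were lower in both, by -0.70 and -0.50, with a median difference of -0.30 (camera, adjusted p = 0.00366, adjusted p = 0.438 with an estimated correlation). ER chaperone genes were lower in both, by -0.80 and -0.62, with a median difference of -0.24 (camera, adjusted p = 0.0335, adjusted p = 0.840 with an estimated correlation). Markers of macrophages, T cells, red cells and NK cells were higher in both splenic flox/- libraries and not in the MPC-11 libraries, and no explanation for the 4 differences was tested. The splenic medians of the 3 lower lists turn direction with libraries scaled to their size alone.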

How the results depend on the processing

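The replicate blocks in splenic cells and in the difference of effect and the scaling to library size alone were chosen only after the result was seen. Counts are given as higher and lower genes. In splenic plasma cells edgeR's 0 and 0 became 433 and 202 with DESeq2, 142 and 19 with limma on the deposited log2 FPKM with a replicate block, and 5 and 0 in a fit of all 10 mouse libraries; they stayed at 0 with RLE scaling, no filter, limma-voom, limma on log2 FPKM without pairing, removal of immunoglobulin genes and each library left out. In MPC-11 edgeR's 2 and 0 became 110 and 49 with DESeq2, 27 and 5 without a filter on low counts, 0 and 0 with limma-voom, 7 and 0 with limma on log2 FPKM, 0 and 0 with a replicate block or with library size alone, and 4 and 2 with all 10 mouse libraries. Leaving out a library gave 1 to 21 higher and 0 to 22 lower. In MM.1S edgeR's 0 and 1 became 195 and 179 with DESeq2, 147 and 142 without a filter, 8 and 8 with limma-voom, 3 and 6 with limma on log2 FPKM, and 103 and 105 with a replicate block. Leaving out a library gave 0 to 677 higher and 0 to 289 lower. A fit without a library assumes that the lone library of its group varies like the other group. The cause of these changes was not tested.

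The 2 count columns that share a name were matched to replicate numbers by their values, the difference of a and b correlating at 0.961 with that of replicates 1 and 2 in the log2 FPKM over 14492 genes. With a replicate block, edgeR then called 0 and 0 genes in splenic plasma cells and 0 in the difference of effect, and 10 lists passed. Correlations of deviations from the group means between like-numbered libraries were -0.01, -0.03 and 0.06 in the log2 FPKM of splenic plasma cells, MPC-11 and MM.1S, and -0.08 and 0.09 in the logCPM of MPC-11 and MM.1S.

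With an estimated correlation, the 9, 8 and 12 gene lists past the threshold in splenic plasma cells, MPC-11 and MM.1S became 0, 0 and 0. That setting also has fewer degrees of freedom, so the loss is not due to correlation alone. For B cell identity in MM.1S the estimated correlation was -0.0462, below the preset 0.01. Its unadjusted p in camera still went from 5.00e-04 to 0.0643. Other estimates lay above the preset, as for the cell cycle in MM.1S (0.712). Leaving out a library gave 8 to 11, 5 to 11 and 12 to 13 lists. Directions of medians turned without empty vector library 1 in MPC-11 for the proteasome (range over libraries left out -0.47 to 0.00836), mitochondrial dynamics (-0.13 to 0.0489), cholesterol synthesis (-0.0356 to 0.27), MYC and ribosome biogenesis (-0.0229 to 0.32) and ribosomal proteins (-0.60 to 0.28, turned also without guide library 1 at 0.18). They turned without empty vector library 2 in MPC-11 for plasma cell identity (-0.33 to 0.0744) and p53 targets (-0.13 to 0.65), and without guide library 2 for the BCL2 family (-0.0228 to 0.11, and -0.0365 without a filter). In MM.1S they turned for oxidative phosphorylation (-0.33 to 0.0254, without empty vector library 2), MYC and ribosome biogenesis (-0.41 to 0.24, without empty vector library 2 or guide library 1), ribosomal proteins (-0.0395 to 0.23, without empty vector library 1 or guide library 1) and glycolysis (-0.63 to 0.0718, without guide library 2). Mitochondrial dynamics in MM.1S, near 0, turned to 0.00572 without a filter and 0.00285 with a replicate block and ranged from -0.0739 to 0.0853 without a library. In spleen they turned for mitochondrial dynamics (-0.0288 to 0.35, without flox/+ library b), ribosomal proteins (-0.24 to 0.43, without flox/- library 1) and Irf4 (-0.33 to 0.76, turned without flox/+ library b and, at -0.03, without flox/- library 2). The difference of effect went from 0 to 181 genes with DESeq2, and to 0 to 1 without a library. Shared calls went from 0 to 14 (spleen and MPC-11), 18 (spleen and MM.1S) and 7 (MPC-11 and MM.1S) with DESeq2's calls. The immunoglobulin difference in MM.1S turned to 0.299 percentage points with constant regions and the joining chain alone. Between TMM, RLE and removal of immunoglobulin genes, the median of all genes moved by less than 0.02 in log2. With library size alone it was 0.98 in spleen, and medians turned there for ER chaperones (0.0940), ER translocation (0.19), plasma cell identity (0.0563), oxidative phosphorylation (0.43), the proteasome (0.67) and the amino acid list (0.56), in MPC-11 for cholesterol synthesis (-0.12), the BCL2 family (-0.0154) and MYC and ribosome biogenesis (-0.0292) and in MM.1S for mitochondrial dynamics (0.00714). Of lists that did not pass and did not turn, medians moved by more than 1.5 times without a library in spleen for p53 targets (0.20 to 0.56), the BCL2 family (0.00756 to 0.36), cholesterol synthesis (0.02 to 0.34), glycolysis (0.24 to 0.41) and MYC and ribosome biogenesis (0.15 to 0.28), in MPC-11 for glycolysis (0.06 to 0.38) and the amino acid list (-0.17 to -0.01) and in MM.1S for the BCL2 family (0.13 to 0.37). Of the values of named genes, 95 in MM.1S, 43 in MPC-11 and 20 in spleen passed the threshold under an alternative and not in edgeR, and 1, 7 and 0 lost it.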

Other observations

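The muscle RNA test, the scaling tests, the tests of the follicular B cell share and the signature tests were chosen only after the result was seen. The 100 genes per direction with the smallest p in one comparison were tested in the others. Genes lower in MPC-11 were lower in MM.1S, 60 of 82 (median -0.20; camera, adjusted p = 3.54e-06, adjusted p = 0.163 with an estimated correlation), and genes higher in MM.1S were higher in spleen, 50 of 64 (median 0.76; camera, adjusted p = 1.26e-05, adjusted p = 0.163 with an estimated correlation). Genes lower in spleen were lower in MPC-11, 72 of 93 (median -0.40; camera, adjusted p = 1.26e-05, adjusted p = 0.403 with an estimated correlation). Genes lower in MM.1S were not lower in spleen, 33 of 78 (median 0.40; camera, adjusted p = 0.191).

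In the reference libraries, bone marrow plasma cells against follicular B cells held 28 of 28 ER chaperone genes higher (median log2 ratio 3.12), 32 of 33 ER translocation genes (2.12) and 27 of 28 amino acid and integrated stress response genes (2.27), and 32 of 32 ribosomal protein genes lower (-1.05). Neutrophil markers summed to 883 CPM in the bone marrow library. In MPC-11, Iglc1 took 17.2% and 7.97% of counts with the empty vector and 16.4% and 15.6% with the guide, while Ighg2b had 22, 5, 0 and 1 counts. MPC-11 is described elsewhere as an IgG2b kappa line, which these counts do not match, so the name of the line rests on the labels. Empty vectors carry no guide RNA, so effects of DNA cutting were not separated from loss of IRF4. On this, p53 targets rose in MM.1S (19 of 20 higher, median 0.70; camera, adjusted p = 3.89e-10, adjusted p = 0.289 with an estimated correlation), while in MPC-11 they did not pass with all libraries (camera, adjusted p = 0.0666) and passed without empty vector library 1 (median 0.65; adjusted p = 0.00733), so cutting stays open in both lines.

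B cell identity genes were higher in the splenic flox/- libraries. Macrophage RNA in flox/- library 1 is argued against by the list's median of 1.88 without that library. The medians of B cell identity and of ER chaperone genes lay 2.53 apart (quartiles 0.75 to 2.96 and -1.04 to -0.69). A factor per library moves all genes alike, so scaling by immunoglobulin content leaves such a distance unchanged. The 2 lists thus moved apart whatever the scaling. The distance does not test scaling as a source of the rise itself, and it does not show which of the 2 lists moved. Follicular B cells in the sort fit the bound written beforehand, since 94.2% of the genes biased to them were higher. The follicular share that each of 23 genes would need was taken from TMM-scaled values over all 10 mouse libraries. It had medians of 7.02% and 14.96% in libraries 1 and 2 (10% to 90% range 0.3304 to 18.96 and 3.29 to 29.1). It is not a share of counts or of RNA, since TMM lowers the follicular values. Irf4 went from 103 to 55.1 CPM in that library. Of 11 genes abundant in the follicular library, 3 need under 0.5 of the median share in both, Fcer2a (1.58% and 2.02%), Cr2 (0.150% and 3.17%) and Spib (2.91% and 4.82%). For these 3 genes the median share is too large. The bound of at least 3 such genes was set after the values were seen and equals the count found. It therefore does not decide whether mature follicular B cells were the source of the whole rise or of a part. Other kinds of B cells and release of B cell genes in plasma cells without IRF4 were not told apart, and the labels give no sort gate.

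ER genes were lower than other genes in the splenic flox/- libraries after TMM scaling. With libraries scaled to their size alone the ER chaperone median was 0.09. This met a bound for scaling by immunoglobulin content as the source of the direction, set after the values were seen. Such scaling moved the median of all genes from 0.09 to 0.98, so the turn follows from that shift and does not decide the source. With immunoglobulin genes removed the ER chaperone median was -0.83. The list took 1.14% and 1.30% of counts with flox/- against 1.14% and 1.21%. It lagged the other genes with size alone too (camera, adjusted p = 2.59e-06). With TMM and an estimated correlation it did not pass (camera, adjusted p = 0.237). For replacement of plasma cell RNA by RNA of other cells, a bound written beforehand was that at least 25% of genes biased to bone marrow plasma cells being higher speaks against it, and the value was 33.3% (exact 95% interval 26.6 to 40.7). By that bound the value spoke against replacement, but the bound was set aside after the value was seen. The list holds genes of other cells such as Itgam and Hmox1, both higher here. Of the written markers of other cells, however, 0 were among its genes measured in spleen. The share also depended on the setting. It was 66.1% with libraries scaled to their size alone. With the planned minimum of 50 CPM in the bone marrow library it was 17.8% (12.7 to 24.0), short of the 25%. Replacement therefore cannot be told apart from lower expression in plasma cells, for lack of a list that other cells leave untouched.

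A few genes known from muscle were higher in MPC-11 with the guide RNA, Mybph with 4981 counts over both libraries where the empty vector had 0, and Myog, which lies close to it on chromosome 1, so these 2 need not be independent. No muscle list was tested; Hrc (DESeq2 adjusted p = 3.15e-07) and Scn4a (DESeq2 adjusted p = 2.64e-08) were higher too but did not pass in edgeR, Scn4a is also among the genes highest in follicular B cells and so not specific to muscle, and Myod1, Myf5 and Des had 0 counts. Muscle cells or muscle RNA in the libraries are argued against by 12 muscle structural genes, whose median count was 0.482% of that of Mybph and whose sums were 1152 and 1525 with the guide against 1356 and 1152. The bounds of that test were set after these counts were seen, and an earlier bound on the median count itself, 24, had decided nothing; a response of plasma cell lines in general to a guide against IRF4 is argued against by MM.1S, where 3 of the 3 genes MYBPH, MYOG and TRIM63 had 0 counts. Clonal outgrowth, a local change at Mybph and Myog, an off-target site and an effect of IRF4 loss in this line may each remain and were not tested.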
